A study of Mus musculus with 17 samples.

How the data were processed

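The samples were E14 mouse ES cells and sperm of 10-week-old C57 mice, each digested with MNase and sequenced as paired-end libraries on an Illumina HiSeq. Per the labels' protocols, sperm came from the cauda epididymis and vas deferens by swim-up and were crosslinked with 1% formaldehyde for 15 min, and permeabilized nuclei were digested for 5 min at 37 °C. The standard digestion used 1000 times less enzyme per cell for sperm than for ES cells, per the labels, and a spin of 5000 g for 5 min parted supernatant from pellet. The number of sperm in the titration digests is not given in the sources used here, so its units cannot be placed on the scale of the standard digestion. Reads were aligned to mm9 with Bowtie and handled with SAMtools 0.1.16, per the submitters' processing notes, which give no Bowtie version. Read filters, the handling of duplicates and of reads that map to several places, and the source of the start sites are not given in the sources used here.

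Of 17 samples, 3 were not analysed here: the unspun ES cell library, the sonicated sperm input and the sperm histone H3 immunoprecipitation. Group, fraction and units were taken from the title and the units field of the labels. The description of the 5-unit and 20-unit pellet samples gives other units than their title and units field, which were followed. Every group held 1 library, so p-values measure how consistent a difference is over doses or series, never over animals or digestions.

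The authors deposited 2 kinds of table, each with 1 row per start site and 200 bins along it. For the ES cell, standard sperm and 4 unspun libraries the deposited values are a signal, a whole-number pileup of fragments per 20 bp bin over 2000 bp to each side, not scaled to depth, from fragments of 135 to 165 bp per the names of the tables. An isolated fragment adds about 22.0 to that pileup. For the supernatant and pellet series the deposited values are whole-number counts of reads touching each bin, not scaled to depth, at 16493 start sites that the authors classed by CpG content as HCP, ICP or LCP, per the file headers, read here as high-, intermediate- and low-CpG promoters. The fragment size of the count tables and the class limits are not given in the sources used here. Where 2 start sites lie close together their windows share DNA, and the shared stretch held the same values for 95.9% to 98.4% of bins at 20 bp per bin in the pileup tables. In the count tables this held for 82.3% to 84.6% of bins at 50 bp per bin and for 2.17% to 11.1% at the 20 bp steps of the header labels, so 50 bp bins over 5000 bp to each side were used. An isolated fragment adds about 2.97 counts, so counts are not independent fragments, and fragment equivalents are table sums divided by 22.0 or 2.97. In the 1-unit count tables isolated signal was narrower, with 79.5% and 85.9% of runs covering 1 or 2 bins, so their fragment equivalents are too low.

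The pileup tables hold 28015 start sites, of which 23456 were used after repeats were taken once, and the count tables hold 16493, of which 16482 were used (10576 high-CpG, 3073 intermediate-CpG and 2833 low-CpG). All 16493 of these start sites are in the pileup tables, and classes were carried over to them. RefSeq transcripts were matched to symbols through a RefSeq gene table of the assembly GRCm38.p6, used for names only, which gave a symbol to 27264 and 16289 start sites. Start-site coordinates are those of the deposited tables, in mm9. Table totals were 37961 to 226365 counts per library in the count tables, and 37.9% to 87.0% of promoters had no count within 1000 bp.

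Each promoter was summed over 1000 bp to each side. The start-site ratio is the mean over the 200 bp upstream of the start site divided by the mean over the flanks, 1000 to 2000 bp on each side, and the downstream ratio uses the 300 bp after the start site; their intervals come from 1000 resamplings of promoters. Shares have exact binomial intervals on fragment equivalents. Reads carry no molecular identifiers, so intervals cover counting error only. The downstream peak is the highest bin after smoothing over 5 bins. The ES cell and standard sperm libraries were compared as log2 ratios of each promoter's share, with exact intervals and no test. Before the log, a pseudocount of 22.0, the pileup of an isolated fragment, was added to each promoter's sum. It matters most at promoters with few fragments, and the exact intervals and pooled ratios were made without it. A list's median was set among 10000 random lists of the same size matched on mean signal in 20 strata. For genes with several start sites the one with the highest mean was used.

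Dose was tested on log2 values against log2 units with 1 slope shared by the 3 series, two-sided and exact over all 13824 orderings of the doses within series; the smallest possible p is 7.2e-05, and 0.0046 with 3 doses per series. Whether supernatant and pellet of a dose come from the same digest is not given in the sources used here, so the orderings were also made with the 2 fractions moved together, which leaves 576 (smallest p 0.0017, or 0.028 with 3 doses). Supernatant and pellet were compared by exact sign flips over 4 dose pairs, two-sided, with a smallest possible p of 0.125. Promoters in the count tables were tested with edgeR 4.0.16 (quasi-likelihood, TMM factors, filterByExpr, Benjamini-Hochberg at 5%) in R 4.3.3, with dose as a factor for the fraction (3 residual degrees of freedom) and fraction as a factor for the dose slope (5 residual degrees of freedom). Alternatives used DESeq2 1.42.0 and limma 3.58.1. The gene lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated one; since the filter left 1 list with 5 or more members for the fraction and none for dose, camera was also run on the 16152 promoters with any count. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest. The edgeR fits were tested on simulated data with 50 promoters changed by each of 2-, 4-, 8- and 16-fold. At the real depth they recovered 0 of 50 at every size within 1000 bp, where the filter let 3 to 8 of the 50 be tested for the fraction and 0 for dose, and no filter 45 to 50, and over the whole span 7 of 50 at 16-fold for the fraction and 0 of 50 for dose. At 100 times the depth and a dispersion of 0.0500 they recovered 37, 50, 50 and 50 for the fraction and 16, 47, 50 and 50 for dose. The exact dose test called 2.75% of 400 simulated series with no trend.

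The 17 gene lists, the tests by promoter, the start-site ratio, the random lists and the naming rule were set before the data were examined. The dose test of profiles and lists, the split by CpG class, the class-matched random lists and the downstream ratio were chosen after seeing the data, because most titration promoters turned out to hold less than 1 fragment. Named genes are, for ES cells against sperm, the 10 highest and 10 lowest log2 ratios among promoters at or above the median in the higher library and at or above the 25th percentile in each (22.3 and 12.0 fragments). For the tests they are the 10 largest changes per direction past the threshold, or the 5 with the smallest p where fewer than 5 pass. Up to 4 members of each list with the highest signal and 8 genes fixed in advance (Prm1, Prm2, Tnp1, Pou5f1, Nanog, Hoxa9, Actb and Gapdh) were looked up as well, and those that the text leaves out are counted in the closing section. Predicted genes and clone names were passed over. For the difference between supernatant and pellet, 1 promoter that this rule names is not reported here. The alternatives were other normalization factors and tools, no filter, other windows, cores, flanks and smoothing, each dose left out, repeats kept, header bin labels, and leaving out the top 1% of promoters. A correction for base composition was not run, because no genome was used here.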

Results

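Micrococcal nuclease (MNase) cuts DNA that is not held by protein, so the fragments it leaves mark packaged DNA. The study sequenced such fragments from E14 cells, a mouse embryonic stem (ES) cell line, and from mature mouse sperm, in which most histones have been replaced by protamines. Its stated purpose was to map nucleosomes and other DNA-bound proteins in both. Of 17 samples, 14 were analysed, each the 1 library of its group, so no value has a replicate. They were the ES cell supernatant, the sperm supernatant of the standard digestion, and sperm digested with rising MNase units in 3 series. The unspun series had 0.5, 2, 10 and 50 units, and the supernatant and pellet series each had 1, 5, 20 and 100 units. The ES cell library held about 2019693 fragment equivalents around start sites and the standard sperm library about 1447953. The unspun libraries held 33972 to 47588, the supernatant libraries 40038 to 76174 and the pellet libraries 12774 to 53159. Within 1000 bp of a start site this gave 33 fragments per promoter in ES cells and 22.1 in standard sperm, but 0.143 to 1.04 in the titration libraries. Single promoters could therefore be read in the first 2 libraries, and pooled promoters in the others. Intervals are 95% and cover counting error or the sampling of promoters only.

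Promoters rich in CpG were depleted of fragments at the start site in both ES cells and sperm of the standard digestion, and more so in sperm. At 10576 high-CpG promoters, the class that holds most housekeeping and developmental genes, the signal over the 200 bp upstream of the start site was 0.346 of the flanks in ES cells (0.337 to 0.356) and 0.291 in sperm (0.284 to 0.298). Over the 300 bp downstream it was 0.316 in ES cells (0.309 to 0.324) and 0.169 in sperm (0.164 to 0.174). The 2833 low-CpG promoters, mostly of tissue-restricted genes, were close to their flanks upstream, at 0.926 in ES cells and 0.853 in sperm, and the 3073 intermediate-CpG promoters lay between, at 0.823 and 0.706. Over all promoters the upstream ratio was 0.560 (0.552 to 0.568) in ES cells and 0.512 (0.504 to 0.519) in sperm.

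High-CpG promoters took 57% of the fragments around classed start sites in ES cells (exact interval 56.8 to 57.1) and 49.4% in sperm of the standard digestion (49.3 to 49.6). Low-CpG promoters took 21% in ES cells and 26.5% in sperm, and intermediate-CpG promoters 22.1% and 24%. Gene by gene, 65.7% of 9591 genes with a high-CpG promoter had a lower share in sperm, with a median log2 ratio of sperm to ES cells of -0.25, against 35.9% of 2629 genes with a low-CpG promoter, whose median was 0.25. The median over 20948 genes was -0.08, and the 2 libraries' sums had a Spearman correlation of 0.61 across genes, which are not independent replicates. This sets 1 library against 1 library of another mouse strain. It also sets crosslinked sperm against ES cells for which the labels give no crosslinking, and the enzyme per cell differed. These differences cannot be told apart from cell type. Against the titration supernatants the direction at high-CpG promoters turned. The log2 ratios to ES cells were 0.04, 0.12, 0.17 and 0.25 at 1, 5, 20 and 100 units, where the standard digestion gave -0.20. The supernatant values are read counts in wider bins with no fragment size given, narrower in isolated signal at 1 unit, so this also compares 2 kinds of table. In the unspun libraries, whose tables are of the ES cell kind, the share was 59.7% at 0.5 units and 69.6% at 50 units, also above 57%.

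Promoters of the chemosensory receptors held a larger share of the fragments in standard sperm than in ES cells. The median log2 ratio was 0.74 over 1097 olfactory receptors, the odour receptors of the nose, of which 1001 were higher in sperm and 96 lower. It was 0.84 over 249 vomeronasal receptors, which detect pheromones, with 225 higher and 24 lower. Clustered protocadherins, adhesion molecules of neurons, had a median of 0.39 with 41 of 57 higher, replication-dependent histone genes 0.34 with 46 of 62 higher, and keratins with keratin-associated proteins, the structural proteins of skin and hair, 0.31 with 69 higher. Developmental regulators outside the Hox clusters, such as Pax, Gata and Sox genes, were lower in sperm with a median of -0.37, and 98 of them were lower. Each of these 6 lists lay outside the central 95% of 10000 random lists of the same size and mean signal, which is a description of these libraries and no test. Against the titration supernatants, whose tables have wider bins, these directions turned at some or all doses when each list was pooled. At 5, 20 and 100 units the log2 ratios to ES cells were -0.14, -0.65 and -1.03 for olfactory receptors, -0.33, -0.82 and -1.51 for vomeronasal receptors and 0.58, 0.94 and 1.14 for developmental regulators, where the standard digestion gave 0.71, 0.57 and -0.36. At 1 unit these lists had not turned, with 0.04, 0.05 and -0.06 in the same order, and each interval held 0. The interval of the vomeronasal receptors also held 0 at 5 units (-0.88 to 0.14). Protocadherins were below 0 at 5 units (-0.91, -1.80 to -0.23) and 100 units (-0.86, -1.36 to -0.38), and at the other doses, as for histone genes and keratins at all 4, the interval held 0.

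The other 11 of the 17 lists lay inside that range. The Hox clusters, which pattern the body axis, had a median of -0.41 (percentile 4.83) with 30 of 39 lower, pluripotency genes -0.24, ribosomal proteins -0.24, and housekeeping and proteasome genes -0.25. Genes of spermatids, the cells that become sperm, had a median of 0.01, with 39 higher and 37 lower. Meiotic and early germ cell genes had 0.03, imprinted genes 0.06, defensins 0.20 and zinc finger proteins 0.00. Marker genes of epididymal epithelium had 0.05 and those of leukocytes 0.07. All cells carry these promoters, so such values cannot show whether the sperm preparation held other cells. Among lists matched on CpG class too, developmental regulators stood at percentile 20.7, inside the range, and meiotic genes at 99.4, above it. Within 200 bp of the start site the developmental regulators' median was 0.04, while their pooled ratio stayed at -0.35 (-0.61 to -0.11).

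Among 11279 promoters deep enough to be named, the highest sperm to ES cell ratio was that of Defb41, a beta-defensin (start site at chromosome 1, 18255219, mm9), with 79 fragments in sperm against 23 in ES cells and a log2 ratio of 2.33 (1.67 to 3.09). The next were mostly receptor and globin genes, with the vomeronasal receptor Vmn1r13 at 1.95, the olfactory receptor Olfr1220 at 1.92, the embryonic globin Hbb-y at 1.92, Skint1 at 1.91 and the globin gene Hbb-bh2 at 1.91. Ankrd7 had 1.88, the microRNA gene Mir383 1.81, the vomeronasal receptor Vmn2r106 1.80 and the taste receptor Tas2r117 1.79. Reads of such families may be shared between near-identical copies, and how the authors treated them is not given in the sources used here.

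The lowest ratio was that of Dcp1a, an mRNA decapping factor (start site at chromosome 14, 31292750), with 15 fragments in sperm against 78 in ES cells and a log2 ratio of -1.69 (-2.71 to -0.99). Ppil2 had -1.64, the ubiquitin-conjugating enzyme Ube2l6 -1.64, the transcription factor Sox15 -1.61, Zcchc10 -1.60, Pdlim1 -1.60, the DNA glycosylase Neil1 -1.60, Uxs1 -1.59, Shq1 -1.57 and Klhl18 -1.56. Of these 10 promoters 9 are of the high-CpG class and Neil1 is of the intermediate one. These ratios depended on the window. Over the whole span Dcp1a had -0.44, Uxs1 -0.59, Pdlim1 -0.69 and Zcchc10 -0.82, and within 200 bp of the start site Uxs1 had 0.14, Neil1 -0.18, Dcp1a -0.66 and Klhl18 -0.74, so their order is not stable. Among the highest, Vmn1r13 had 1.17 and Tas2r117 0.99 over the whole span, and Defb41 1.64, Skint1 2.72, Vmn1r13 3.10 and Hbb-y 3.76 within 200 bp. The values within 200 bp rest on fewer fragments and have no intervals here.

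The pluripotency factor Pou5f1 was lower in sperm, with 9 fragments against 33 and a log2 ratio of -1.20 (-2.55 to -0.20), whereas Nanog had -0.06 (-0.81 to 0.64). Within 200 bp of the start site the values were -2.82 and -1.09, without intervals. That window holds few fragments per promoter, with 21784 in ES cells and 13806 in sperm over all 3073 intermediate-CpG promoters, so these 2 values are not read as differences. Actb, the cytoplasmic actin gene, had 7 fragments against 30 and a ratio of -1.29 (-2.95 to -0.31), and Gapdh had -0.28 (-1.56 to 0.76). The protamine genes Prm1 and Prm2 had -0.24 (-1.29 to 0.69) and -0.25 (-1.05 to 0.49), and the transition protein gene Tnp1 had -0.04 (-0.85 to 0.66), so no difference was detectable at this depth for the genes whose products replace histones. Hoxa9 had 0.68 (-0.11 to 1.45). The deepest members of the fixed lists went both ways. Olfr1134 had 1.28, Krtap19-4 1.25, Vmn1r21 1.12, the epididymal sperm-binding protein gene Bsph2 0.84, Pcdhb19 0.78, the meiotic gene Tex15 0.67 and the sperm mitochondrial protein gene Smcp 0.64, and their intervals lay above 0. Those of Tex101 at -1.08, Rpl4 at -0.77, Rps26 at -0.69 and the vomeronasal receptor Vmn1r235 at -0.48 (-1.01 to -0.02) lay below 0, though Rpl4 had 0.04 within 200 bp and Tex101 -0.42 over the whole span. The CpG classes differed from 0 themselves. The intervals of Tex15 (0.15 to 1.18) and Smcp (0.12 to 1.18) held the low-CpG median of 0.25. That of Rps26 (-1.42 to -0.05) held the high-CpG median of -0.25. The other intervals listed here left out the median of their class, that of Bsph2 narrowly (0.27 to 1.42).

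The MNase titration asks how the sperm fragments change with the degree of digestion. In all 3 series, high-CpG promoters went from depleted or near their flanks at the lowest dose to enriched at the highest. Over the 300 bp downstream of the start site, their signal over the flanks rose from 0.560 at 0.5 units to 1.88 at 50 units in the unspun series, from 0.630 at 1 unit to 1.69 at 100 units in the supernatant, and from 0.825 to 2.17 in the pellet, which are 3.36-fold, 2.68-fold and 2.64-fold increases. The log2 slope shared by the 3 series was 0.216 per doubling of units, with a two-sided exact p of 1.4e-04 over 13824 orderings of the doses (adjusted p = 4.7e-04 over 10 measures). Upstream of the start site the slope was 0.098 (exact p = 7.2e-04, adjusted 0.0010), with 0.726 rising to 1.36 in the unspun series and 0.968 to 1.68 in the pellet, while the supernatant was lowest at 20 units (0.848, 0.917, 0.838 and 1.13) and had the smallest slope of the 3, at 0.052. Without the highest dose of each series the upstream slope was 0.057 and missed the threshold (exact p = 0.051), while the downstream slope kept an exact p of 0.0093.

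**Figure D1:**
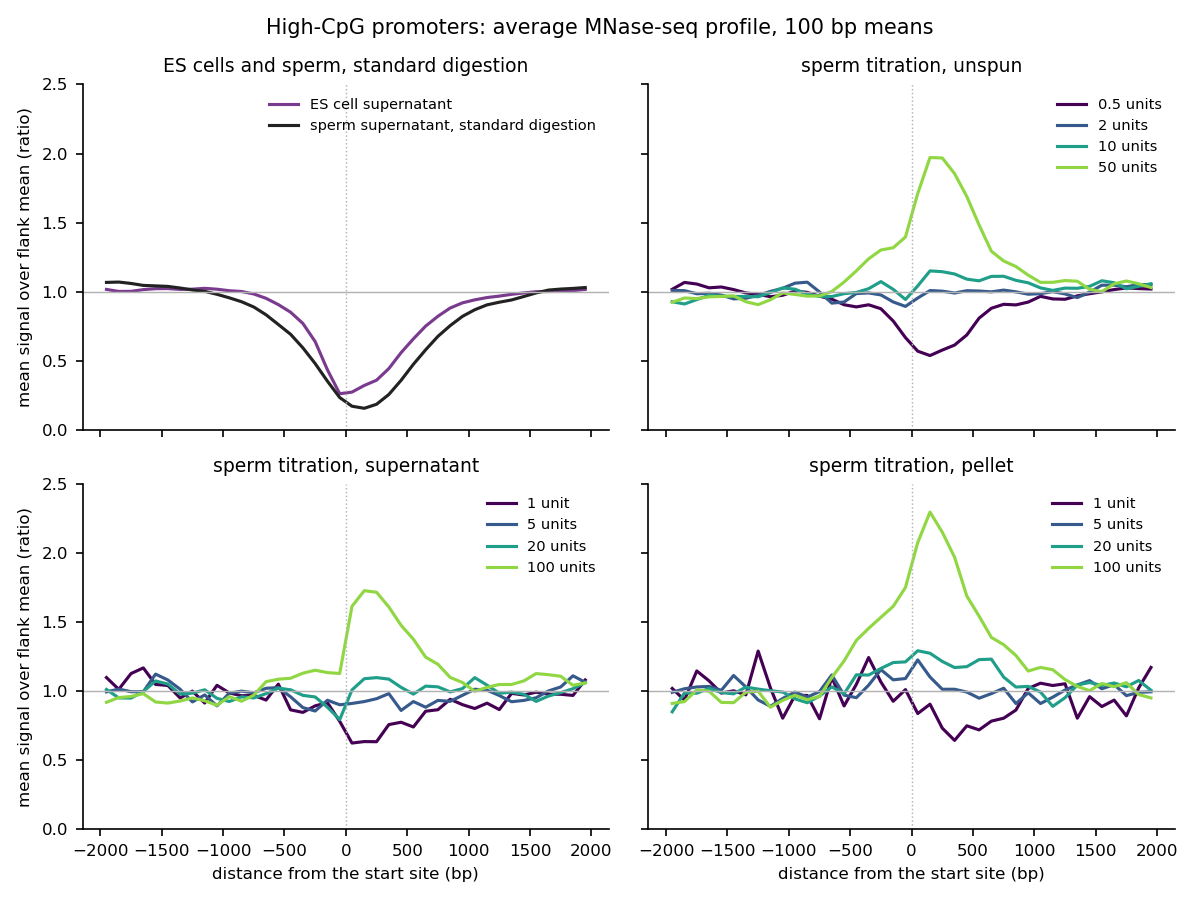
Average profile over high-CpG promoters in each library, in 100 bp means, with distance from the start site in bp on the x axis and mean signal divided by the mean of the flanks (1000 to 2000 bp on each side) on the y axis; each line is 1 library. ES cells and standard sperm dip to 0.245 and 0.153 near the start site, whereas the 50-unit unspun and 100-unit supernatant and pellet lines peak downstream of it.

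The same titration moved signal from CpG-poor to CpG-rich promoters. The share of high-CpG promoters rose from 59.7% (58.9 to 60.5) to 69.6% (68.8 to 70.4) in the unspun series, from 58.7% to 67.9% in the supernatant and from 60.8% to 72.1% in the pellet. Low-CpG promoters fell from 19.3% to 13.9%, from 21% to 15.5% and from 19.8% to 12.8%, and intermediate-CpG promoters fell from 21% to 16.5%, from 20.3% to 16.6% and from 19.4% to 15.2%. The shared log2 slopes were 0.033, -0.077 and -0.046 per doubling for the high, low and intermediate classes, with two-sided exact p of 1.4e-04, 1.4e-04 and 2.2e-04, and each series had the same direction. The 1-unit supernatant and pellet libraries stood apart in their fragments, since 79.5% and 85.9% of isolated signal runs covered 1 or 2 bins, against 3.31% to 6.28% at the other doses of those series; without the lowest dose of each series the high-CpG slope was 0.031 (exact p = 0.0046). Low-CpG promoters also gained at their own start sites relative to their flanks, with a slope of 0.047 upstream (exact p = 0.0019) and 0.074 downstream (exact p = 5.8e-04), as did intermediate-CpG promoters with 0.044 (exact p = 0.0054) and 0.088 (exact p = 0.0017). Without the lowest dose of each series the slopes of intermediate-CpG promoters were 0.026 (exact p = 0.19) and 0.075 (exact p = 0.065) and the upstream one of low-CpG promoters was 0.039 (exact p = 0.065), which ended those calls; the latter was 0.038 without the highest dose (exact p = 0.093). The orderings treat doses as exchangeable within a series and say nothing of the spread between animals or digestions.

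**Figure D2:**
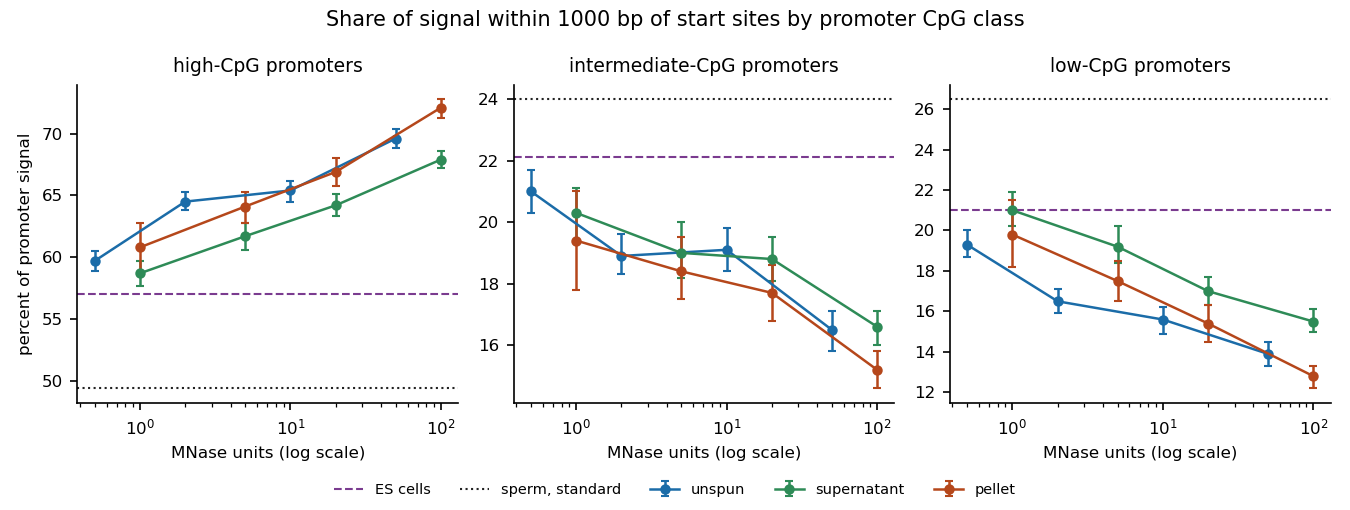
Percent of the signal within 1000 bp of classed start sites that falls at high-, intermediate- and low-CpG promoters (y axis, percent) against MNase units (x axis, log scale), with 1 library per point and exact binomial 95% intervals as bars; dashed and dotted lines mark ES cells and standard sperm. High-CpG promoters rise to 69.6%, 67.9% and 72.1% in the 3 series, and standard sperm at 49.4% lies below every titration library.

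Vomeronasal receptors lost share as digestion went on, and olfactory receptors fell and developmental regulators rose with less certainty. Promoters of the developmental regulators outside Hox rose 1.99-fold from the lowest to the highest dose in the unspun series, 2.29-fold in the supernatant and 1.42-fold in the pellet, with a shared log2 slope of 0.145 per doubling (two-sided exact p = 0.0080, adjusted p = 0.046 over 17 lists). The 850 olfactory receptor promoters fell to 0.642, 0.473 and 0.443 of their first share, with a slope of -0.142 (exact p = 5.1e-04, adjusted p = 0.0043), and the 65 vomeronasal receptor promoters to 0.481, 0.339 and 0.362, with a slope of -0.203 (exact p = 7.2e-05, the smallest these orderings allow, adjusted p = 0.0012). These orderings treat supernatant and pellet as separate series, although both fractions of a dose may come from 1 digest. With the 2 reordered together (576 orderings) vomeronasal receptors alone passed (exact p = 0.0017, adjusted p = 0.030), and olfactory receptors and developmental regulators did not (exact p = 0.012 and 0.010, adjusted p = 0.069 and 0.069). In the pellet the developmental regulators were lower at 5 units than at 1 unit, with 0.569 and 1.01 times the share of an average promoter. Without the highest dose the slopes were 0.136, -0.148 and -0.139. Of the 17 lists, 0 passed the adjusted threshold without the second or the highest dose. Without the lowest 2 passed (vomeronasal receptors and housekeeping genes), as did 2 without the third (vomeronasal and olfactory receptors). The developmental regulators passed in none of the 4. With 3 doses per series the smallest possible exact p is 0.0046, at which a list cannot pass on its own when adjusted over 17 lists. A failure with a dose left out therefore cannot decide whether a call holds. Within 200 bp of the start site the slope of the developmental regulators was 0.079 and no longer passed.

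The other 14 lists did not pass, with adjusted exact p from 0.25 to 0.95. Hox promoters had a slope of 0.063 (exact p = 0.19, adjusted p = 0.30), pluripotency genes 0.067, ribosomal proteins 0.059, meiotic genes 0.044 and imprinted genes 0.028. Spermatid genes had -0.024, housekeeping and proteasome genes -0.046, protocadherins -0.049, keratins -0.017, defensins -0.022, histone genes -0.007 and zinc finger proteins -0.022. Epididymal epithelium had -0.045 and leukocytes -0.057, neither past the threshold. Within 2000 bp of the start site pluripotency genes (0.121, adjusted exact p = 0.039), housekeeping genes (-0.056, 0.032) and defensins (-0.059, 0.039) passed as well. In limma's camera test over 16152 promoters of the supernatant and pellet libraries, developmental regulators went up with dose (adjusted p = 8.0e-04 at the preset correlation) and olfactory and vomeronasal receptors went down (adjusted p = 2.1e-06 and 9.2e-06). Camera takes the 8 libraries as independent, and with an estimated correlation those calls were lost, at adjusted p = 0.50, 0.19 and 0.19, and the other 14 lists had 0.60 or more at the preset value.

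**Figure D3:**
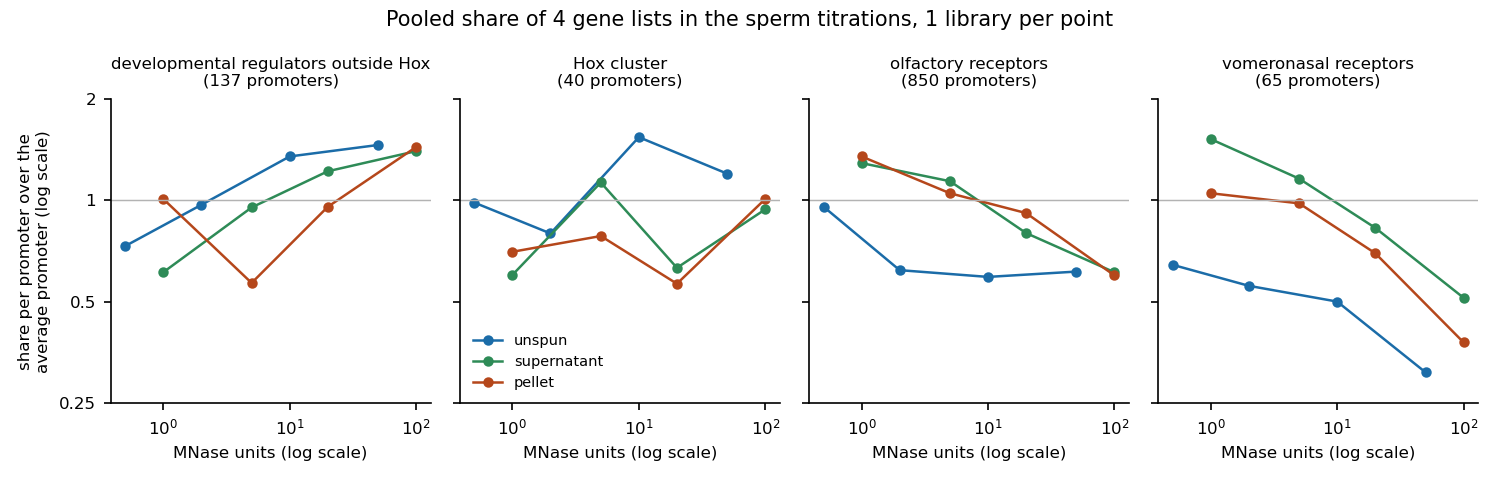
Share per promoter of 4 gene lists over that of the average promoter (y axis, log scale) against MNase units (x axis, log scale) in the sperm titrations, with 1 library per point and no error bars. Developmental regulators (slope 0.145) end higher and olfactory and vomeronasal receptors lower than they began in the 3 series, and the Hox clusters have a slope of 0.063.

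Single promoters gave no call for dose. In edgeR's quasi-likelihood test on the supernatant and pellet counts, 0 of 7 promoters that passed the filter changed with dose at an adjusted p of 0.05, 0 had an unadjusted p under 0.05, and DESeq2 also called 0 with 1 at an unadjusted p under 0.05. The promoters with the smallest p did not pass. Upward slopes were 0.23 for Hjurp, a chaperone of centromeric histone, 0.15 for Sfi1, a centrosome protein, 0.06 for Hsd11b1 and 0.03 for Stx4a, and downward slopes were -0.65 for Gtf2e1, a general transcription factor, and -0.26 for Fbxo7, with adjusted p from 0.41 to 0.92. Without the filter 0 of 16152 promoters passed, with 1354 at an unadjusted p under 0.05, and over the whole 5000 bp to each side 2 of 8365 passed (253 unadjusted), Sfi1 and Tmem125, named after their values were seen. Without the filter, simulated 2- to 16-fold changes within 1000 bp were recovered for 0 of 50 promoters each, so a change at most single promoters would be missed.

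Supernatant and pellet were compared at the same 4 doses to ask whether centrifugation splits the sperm fragments by where they come from. High-CpG promoters held a larger share in the pellet at 4 of 4 doses, 1.04-fold on average, and low-CpG promoters a smaller one at 4 of 4 doses, 0.893 of the supernatant. Signal upstream of the start site at high-CpG promoters was 1.31-fold higher in the pellet on average, from 0.968 of the flanks against 0.848 at 1 unit, the smallest difference, to 1.68 (1.58 to 1.79) against 1.13 (1.07 to 1.2) at 100 units, the largest, and downstream signal was 1.24-fold higher, both at 4 of 4 doses. With 4 pairs of libraries the two-sided exact sign-flip test cannot go below 0.13, which is the p of each of these differences, so none can pass 0.05. Intermediate-CpG promoters had 1.08-fold upstream at 3 of 4 doses and low-CpG promoters 1.02-fold at 2 of 4 doses (exact p = 0.25 and 0.75).

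The gene lists gave no call between the fractions. Pluripotency promoters were higher in the supernatant by 0.74 log2 on average, vomeronasal receptors by 0.37 and spermatid genes by 0.25, each at 4 of 4 doses, with an exact p of 0.13, the smallest possible. Olfactory receptors differed by -0.03 and developmental regulators by 0.08, each split 2 to 2 over the doses. In limma's camera test none of the 17 lists passed for the fraction, with adjusted p from 0.39 to 1.0 at the preset correlation, nor for a difference in dose slope between fractions, from 0.31 to 0.96.

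Among single promoters that passed the filter, 0 differed between supernatant and pellet in edgeR's quasi-likelihood test, 1 had an unadjusted p under 0.05, and DESeq2 called 0 with 1 at an unadjusted p under 0.05. For a difference in dose slope the numbers were 0 in edgeR with 0 unadjusted and 0 in DESeq2 with 1 unadjusted. Of the 9 olfactory receptors tested, the only list with 5 or more members, 0 passed, adjusted over the list alone as well, and without the filter the same held for each of the 17 lists. Sfi1 had 93, 76 and 90 counts in the supernatant at 1, 5 and 20 units and 30, 24 and 60 in the pellet, with more in both at 100 units and a log2 difference of 1.23 over the 4 doses that did not pass (adjusted p = 0.96). In edgeR it passed, higher in the supernatant, with RLE in place of TMM factors, without the 5-unit pair and without the 100-unit pair. It also passed, lower in the supernatant, with 1 count per run of filled bins. The Sfi1 promoter had the highest signal in each library analysed, ES cells included. Whether reads that map to several places contribute to its counts was not tested. The others that ranked first by p in their direction did not pass (edgeR adjusted p = 0.96) and rested on few counts. On the supernatant side these included Sprr2d with 27 in all, Zfyve26 with 27 in all and Rad51ap1 with 40 in all. On the pellet side they were Olfr918 with 21, the histone gene H4c3 with 16, Abtb2 with 25, Wdsub1 with 25 and Hagh with 22.

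A peak of signal stood downstream of the start site at the highest dose of each series. Over all promoters its height over the flanks was 1.71 (1.63 to 1.78) at 170 bp in the unspun series at 50 units, 1.61 (1.54 to 1.67) in the supernatant and 2.03 (1.97 to 2.13) in the pellet at 100 units, both in the bin from 150 to 200 bp. In the unspun series the height was 1.05 at 2 units and 1.2 at 10 units. ES cells and standard sperm had no peak between the start site and 300 bp, since their signal was highest at the edge of that window, at 0.567 and 0.428 of the flanks. Further peaks downstream moved with the smoothing and are not given as a spacing.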

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

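The settings chosen after the results were seen were those on bin labels, touches counted once, the CpG class, pooled shares, dose slopes, gene lists by dose, each dose left out of the slopes, fractions reordered together, named genes, and the whole span with no filter; the others were set before the data were examined. Over all settings run, 718 values stayed within their interval or kept their direction and side of the threshold, 83 moved beyond their interval, 15 gained and 23 lost a threshold in the same direction and 49 reversed. The slopes of the high- and low-CpG shares kept direction and side in every setting run, and that of the intermediate-CpG share in all but 1, with the fractions reordered together and the lowest dose left out (exact p 0.056). Of 95 named genes, 95 kept their ratio within its interval after scaling to the median promoter, 88 over the whole span and 61 within 200 bp; of those whose interval left out 0, 2 reversed within 200 bp, Uxs1 (0.14) and Rpl4 (0.04). Genes whose interval held 0 changed sign there too, such as Hoxc6 (0.75), Lhx8 (-1.15), Fbxo15 (1.27), Psmd4 (1.25) and H2bu2 (1.66), and are counted as moved or kept. Titration promoters held 0.143 to 1.04 fragments each, and each group had 1 library. Where no cause is given, the cause was not tested.

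Promoters called between supernatant and pellet numbered 0, but 1 with RLE in place of TMM factors in edgeR and 0 to 1 with each dose left out. With 1 count per run of bins over the whole span, where 3 promoters were tested, 1 was called. Each was Sfi1, higher in the supernatant except in the last. Dose called 0, but 2 over the whole span, 1 over the whole span with no filter, and 1 in the 4 unspun libraries alone with limma. Dose gave no value within 200 bp, where too few promoters passed the filter. The correction for base composition and a fit of all 12 titration libraries were not run, the latter because unit and layout differ. Other pseudocounts for the single-promoter ratios of sperm to ES cells were not tried.

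The start-site ratio of ES cells, 0.560, was 0.541 as the mean of each gene's own profile, 0.524 from 150 bp upstream to 50 bp downstream, 0.597 from 300 bp upstream to 100 bp downstream and 0.541 with every deposited start site. That of standard sperm, 0.512, was 0.471, 0.471, 0.520 and 0.495 in the same settings, 0.502 without the top 1% of genes and 0.502 with the upstream flank alone. With each dose left out, the upstream slope was 0.057 to 0.115 for high-CpG, 0.026 to 0.048 for intermediate-CpG and 0.038 to 0.050 for low-CpG promoters, the downstream slope of intermediate-CpG promoters was 0.075 to 0.092, and the log2 ratio of pellet to supernatant upstream of low-CpG promoters was -0.02 to 0.09. At 100 units the downstream peak moved with 9-bin smoothing to 275 bp in the supernatant and 225 bp in the pellet (height 1.92), and its height with no smoothing was 1.72 and 2.14.

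Over the whole span, median log2 ratios of sperm to ES cells were -0.46 for Hox, now outside the random lists, -0.29 for developmental regulators, now inside, and 0.31 for defensins, now outside. Within 200 bp they were 0.04 for developmental regulators, 0.51 for defensins, now outside, and 0.29 for protocadherins, now inside, but pooled they were -0.35 (-0.61 to -0.11) for developmental regulators and -0.04 (-0.32 to 0.25) for defensins. Pooled ratios over the whole span and within 200 bp were -0.13 and -0.31 for high-CpG, 0.09 and 0.04 for intermediate-CpG and 0.28 and 0.30 for low-CpG promoters. With the titration supernatants at 1, 5, 20 and 100 units in place of standard sperm they were 0.04, 0.12, 0.17 and 0.25 for high-CpG, -0.12, -0.21, -0.23 and -0.41 for intermediate-CpG, 0.00, -0.13, -0.30 and -0.44 for low-CpG promoters, and -0.34, -0.91, -0.15 and -0.86 for protocadherins. At the same 1, 5, 20 and 100 units they were -0.06, 0.58, 0.94 and 1.14 for developmental regulators. They were 0.04, -0.14, -0.65 and -1.03 for olfactory and 0.05, -0.33, -0.82 and -1.51 for vomeronasal receptors. Over these doses histone genes had -0.60, -0.04, -0.06 and 0.21, Hox -0.49, 0.42, -0.42 and 0.16, and keratins 0.22, 0.22, -0.02 and 0.05. Each of these intervals held 0.

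List slopes with dose within 200 bp were 0.079 for developmental regulators, -0.008 for Hox, -0.066 for ribosomal proteins, -0.039 for imprinted genes and 0.013 for epididymal epithelium. Keratins had 0.004 within 2000 bp and 0.003 with header bins, and histone genes 0.011 without the top 1% of promoters. With each dose left out the slopes were 0.136 to 0.185 for developmental regulators, -0.148 to -0.126 for olfactory and -0.255 to -0.139 for vomeronasal receptors, -0.111 to 0.003 for housekeeping genes, -0.023 to 0.076 for meiotic genes, -0.069 to 0.038 for epididymal epithelium, -0.023 to 0.005 for keratins, -0.042 to 0.032 for defensins, -0.074 to 0.060 for protocadherins and -0.156 to 0.063 for histone genes. Of the 17 lists, 3 passed. Within 200 bp 1 did, and within 2000 bp 6 (with pluripotency genes, housekeeping genes and defensins). With a dose left out 0 to 2 passed, where the smallest possible exact p of 0.0046 is too high for a list to pass on its own. With supernatant and pellet reordered together 1 list passed, the vomeronasal receptors, and the slopes of 0.145 for developmental regulators and -0.142 for olfactory receptors no longer did, whereas the 10 profile and share measures kept adjusted exact p of 0.0058 to 0.014. Without the lowest dose as well, where the smallest possible exact p is 0.028, 5 of these 10 missed 0.05: the start-site ratio over all promoters (0.056), the intermediate-CpG share (0.056), the upstream ratio of intermediate-CpG (0.14) and low-CpG promoters (0.17) and the downstream ratio of intermediate-CpG promoters (0.17).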

Other observations

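All tests in this part were chosen after the data were seen, and those of a few high promoters and of the CpG class of developmental regulators and olfactory receptors before their own values were.

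Sfi1, which encodes a centrosome protein, had the promoter with the highest signal in each of the 14 libraries. In ES cells its sum was 29507, which is 8.41 times that of the next promoter, and in standard sperm it was 18750, or 5.07 times the next. In the titration libraries it stood 1.09 to 4.65 times above the next and 22.8 to 70.4 times above the mean promoter. Sfi1 was thus highest in ES cells and sperm alike, at every dose and in each fraction. How reads that map to several places were handled is not given in the sources used here. Whether such reads raised its signal was not tested, so its height cannot be read as packaging. Promoters on the X chromosome held less signal than autosomal promoters of the same class. In ES cells they stood at 0.547, 0.577 and 0.603 of the autosomal level for the high-, intermediate- and low-CpG classes. In standard sperm they stood at 0.582, 0.621 and 0.570. The signal was not corrected for the number of X copies in the cells, so these values do not measure packaging. The share per promoter of the X chromosome had a slope of -0.067 per doubling of units. Its two-sided exact p of 0.010 did not pass when adjusted over 20 chromosomes (0.21). Within 200 bp of the start site the histone genes stood further above ES cells in standard sperm, with a median log2 ratio of 1.09 and 47 of 57 genes higher.

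The share of high-CpG promoters rose with MNase units at a slope of 0.033. If a few promoters with very high counts made the rise, it should fade without them, yet the slope was 0.032 without the top 1% of promoters. Counting each bin at most once, which takes out stacked fragments, also left 0.032. Leaving out the lowest dose of each series left 0.031. Isolated signal at that dose was narrower in the supernatant and pellet series, but not in the unspun one. These slopes each had an exact p under 0.05. These values speak against those sources as the whole of the rise. Base composition was not tested, since MNase prefers AT-rich DNA and no genome was used here, so a preference of the enzyme may contribute, as may a loss of histone-free DNA or a difference in packaging, and these cannot be separated with these tables.

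Developmental regulators rose and olfactory and vomeronasal receptors fell with MNase units, and their CpG classes differ in the same sense, with most developmental promoters in the high class and 650 of 850 olfactory promoters in the low class. Against random lists of the same classes and mean signal, the slope of the developmental regulators stood at percentile 100, where the central 95% of lists ended at 0.078, and those of the olfactory and vomeronasal receptors at percentile 0 and 0; housekeeping genes (0.552), protocadherins (0.473) and zinc finger proteins (0.710), whose dose tests did not pass, lay below the range too. Random lists of the same classes thus did not reach the 3 slopes. They were drawn promoter by promoter, so they do not keep gene clusters together and their range may be too narrow. CpG content within a class was not matched, so they cannot decide whether CpG content is enough. With supernatant and pellet reordered together the calls for developmental regulators and olfactory receptors ended (adjusted exact p 0.069 and 0.069). Base composition within a class remains open, as do the packaging of these promoters in sperm and, for the receptors, reads shared between copies, so the ordering may be technical or biological.

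High-CpG promoters held less of the signal in standard sperm than in ES cells, by -0.20 log2. The degree of digestion cannot be told apart from cell type here. The log2 ratio to ES cells moved by 0.21 over the 4 supernatant doses, about as much as the difference itself. From 5 to 100 units it went from 0.12 to 0.25, and the 1-unit library, at 0.04, was the one with narrower isolated signal. However, no dose lay on the side of standard sperm, and the titration units cannot be placed on the scale of its digestion. These values therefore cannot decide whether a lighter digestion in that library accounts for part or all of the difference. The strain, the crosslinking, which the labels give for sperm only, and the cell type stay untested.

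For single promoters between supernatant and pellet the real grouping called 0, which each of the 32 splits of the 8 libraries that could be fitted must reach. Those splits therefore say nothing about chance here, and the highest of the others gave 1.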
